A study of Mus musculus with 38 samples.

How the data were processed

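Lung RNA of wild-type (WT) C57BL/6 mice and of mice labelled as knockouts of the interleukin 1 receptor type 1 gene Il1r1 (KO) was measured on 38 arrays. Per the labels, the mice were female and received a single intratracheal dose of 162 µg of Mitsui-7 multi-walled carbon nanotubes (MWCNT) in 50 µl, or a dose of 0 (control). Lungs were taken after 1 or 28 days. The labels do not name the control vehicle. The 8 groups of genotype, day and exposure held 5 arrays each, except WT day 28 controls and KO day 1 exposed lungs with 4. Replicates are numbered within a group in the order of the records and do not pair samples across groups. The labels do not state that each array is a separate mouse, so the p-values measure the spread between samples.

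Each array compared 200 ng of lung RNA in the Cy5 dye with a reference RNA pool of 11 mouse cell lines in the Cy3 dye, with no dye exchange. The deposited scanner files hold the median pixel intensity of every spot and of its local background in each channel. Per the file headers the authors used Agilent Feature Extraction 11.0.1.1, and the same files hold processed intensity values with background subtracted and dyes normalized by that program. The deposited value table holds log2 ratios per probe with column medians from -0.044 to -0.008. All 55681 probes of that table matched a probe of the scanner files. Each of its 38 columns correlated best across probes with the log2 ratios computed here for its own array, at r from 0.989 to 0.996.

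The log2 ratio of Cy5 over Cy3 was computed with limma 3.58.1 in R 4.3.3 from the median signals. The plan named mean signals, which the files used here do not contain, so that choice could not be followed. Background was corrected with the normexp method and an offset of 50, which draws the ratios of dim spots towards 0, and each array was normalized by loess, which assumes that rises and falls balance at each intensity. Spots marked as outliers by the scanner program were left out and spots of one probe were averaged. A probe was kept if it was well above background in Cy5 on at least 4 of the 38 arrays, and 39580 of 55681 probes passed. Genes were named by matching the RefSeq accession of a probe to a table of RefSeq symbols. One symbol was found for 28026 probes, 25885 probes had no RefSeq accession, and 1770 had an accession with no symbol in that table. The probe with the highest average intensity stood for its gene. This left 28173 genes and unnamed transcripts, 17125 of them with a symbol. Between 29954 and 44279 probes per array were well above background in Cy5, and the number of arrays per group limits the precision.

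A limma model with one mean per group was fitted to all 38 arrays, and moderated tests were made for 10 comparisons. These were the exposure effect in each genotype and day, the difference between genotypes in that effect at each day, the difference between days in that effect for each genotype, and KO against WT controls at each day. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, with no fold minimum. Values are log2 fold changes ± the standard error (SE) of the model.

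Gene lists numbering 31 were fixed before the data were examined, as were the comparisons, the filter, the threshold and the rule for named genes. The programme lists were neutrophil chemokines, monocyte and lymphocyte chemokines, acute phase, IL-1 system, NF-kB feedback and targets, type 2 and STAT6, extracellular matrix and fibrosis, interferon response, NRF2 and oxidative stress, cell cycle, lysosome and lipid-handling phagocyte, cholesterol synthesis, complement, and the circadian clock. The marker lists covered neutrophils, alveolar macrophages, monocytes and interstitial macrophages, eosinophils with mast cells and basophils, T cells, B and plasma cells, NK and cytotoxic cells, dendritic cells, alveolar type 2 and type 1 cells, club and ciliated cells, injured or transitional epithelium, endothelium, fibroblasts with smooth muscle, cardiac muscle, blood cells and adipose tissue. A list of 17 liver markers was added after the data were seen. The mean log2 ratio of these 17 genes on an array is called the liver marker score.

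Lists were tested with fry of limma, whose p asks whether the members move on balance one way and which does not compare the list with other genes. Its p-values were adjusted over the 31 fixed lists within a comparison, and those of the liver list are not part of that family. The camera test with a preset and with an estimated correlation between genes was run beside it. Members were also counted after adjustment over the list alone.

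The rule for named genes took Il1r1, a fixed panel of 30 genes, the 8 largest rises and 6 largest falls of each exposure comparison, and the 10 genes of smallest p in each genotype and day difference. It also took the 10 largest changes of each control comparison and up to 4 called members of each list. Cxcl2 of the panel was not tested, since its 1 probe was above background on 3 arrays. Genes named outside this rule are said to be so, and 3 genes that meet it are not reported here.

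The alternatives were the processed intensities, median centring in place of loess, a further quantile step on average intensity, Cy5 alone, other filters, all probes or their mean, a fold minimum of 1.5, slide as a fixed or random block, the deposited log2 table, a fit to the groups of the comparison alone, and leaving out each array in turn. After the data were seen, fits with the liver marker score as a covariate and without the 6 arrays with a score above 2.81 (the mean plus 1 SD) were added, as was the deposited table for single genes. Single genes were not followed under the other filters, all probes or their mean, slide as a random block, or the fit to the groups of the comparison alone. The arrays lay on 6 slides, and most groups were spread over 4 or 5 of them.

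The model fit was tested on simulated ratios with known changes placed in random genes. At a log2 change of 1 it called 92.5% of the changed genes in WT day 1 exposure with 5 false calls, and 82.1% with 8 false calls for the genotype difference at day 1. At a log2 change of 0.5 the latter figure was 29.9%. The simulated noise was independent between genes and arrays and was placed on normalized ratios, with no slide effect. These figures hold for that setting and can be too favourable for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.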

Results

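Lungs of WT and Il1r1 KO mice were compared 1 and 28 days after a single dose of 162 µg of Mitsui-7 carbon nanotubes, a long, rigid fibre type used as a reference material for lung inflammation and fibrosis. Il1r1, the receptor through which IL-1 alpha and IL-1 beta signal, has 1 probe on the array, whose position relative to the deleted part of the gene is not known here. Its log2 ratio did not differ between unexposed KO and WT lungs (0.02 ± 0.11 SE at day 1, n = 5 and 5, adjusted p = 0.986), so this probe does not check the genotype labels. After exposure Il1r1 rose at day 1 in WT lungs (0.68 ± 0.11, adjusted p = 2.16e-05). In KO lungs it stood at 0.40 ± 0.11 (adjusted p = 0.0298), a call lost without any of 6 arrays (adjusted p up to 0.127, without KO_1d_MWCNT 3), and the 2 changes did not differ (adjusted p = 0.909). Genes of the liver, an organ removed in the same procedure, varied widely between lung samples. The liver marker score was 2.79 ± 1.69 (SD, n = 5) in WT exposed and 1.17 ± 0.892 (n = 5) in WT control lungs at day 1. In KO lungs at day 1 it was 0.967 ± 0.474 (n = 4) after exposure and 2.70 ± 0.55 (n = 5) in controls. Marker list means of other tissues varied as widely at day 1. The SD was 1.995 for adipose tissue in KO controls and 1.819 for cardiac muscle in WT controls. For cardiac muscle WT_1d_control 5 stood 3.93 above the mean of all arrays. No fit adjusted for these tissues.

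At day 1 in WT lungs, exposure was followed by a steep rise of acute phase genes, chemokines and cytokines. Saa3, an acute phase serum amyloid made in inflamed tissue, rose by 6.67 ± 0.41 on the log2 scale (102-fold, n = 5 and 5), from between -3.85 and -3.07 in control arrays to between 2.66 and 3.91 in exposed ones. The metal-binding Mt2 rose by 4.60 ± 0.28, the protease inhibitor Timp1 by 4.05 ± 0.31, Serpina3m by 3.96 ± 0.27, and Saa1 and Saa2 by 3.94 ± 0.27 and 3.86 ± 0.27. Il6, a driver of the acute phase response, rose by 3.58 ± 0.35, and the monocyte chemokines Ccl7 and Ccl2 by 3.54 ± 0.36 and 3.24 ± 0.29. The neutrophil chemokines Cxcl1 and Cxcl5 rose by 3.26 ± 0.24 and 3.01 ± 0.36. Cyp4a14, a fatty acid hydroxylase of liver and kidney, rose by 3.80 ± 0.66, a call lost without the arrays of high liver marker score (adjusted p = 0.231). The largest falls among called genes with an established symbol were those of Gbp4, an interferon-induced GTPase (-1.57 ± 0.36), Colq, the collagen tail of acetylcholinesterase (-1.57 ± 0.24), Ecm2 (-1.41 ± 0.19), Gbp3 (-1.39 ± 0.21) and the sodium channel gene Scn3a (-1.25 ± 0.21).

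Of 24 measured acute phase genes, 22 rose and 2 were not called (23 rose when adjusted over the list alone; fry adjusted p = 9.53e-14), and the list mean was higher on 4 of 4 slides that held both groups. The acute phase list includes liver-made genes, Hpx and Fgg among them. The liver marker list rose in WT day 1 exposure (7 of 17 members called, fry p = 0.0109, p = 0.177 with an estimated correlation), being higher on 2 of 4 slides. Among NF-kB feedback and target genes 17 of 23 rose (18 when adjusted over the list alone; adjusted p = 6.39e-10), among them the NF-kB regulator Bcl3 (1.79 ± 0.23), the adhesion molecules Selp (1.58 ± 0.16) and Icam1 (1.12 ± 0.16), and the cytokine Csf2 (1.18 ± 0.16). Monocyte and lymphocyte chemokines rose for 9 of 14 members (9 up and 1 down when adjusted over the list alone; adjusted p = 1.11e-07). Neutrophil chemokines and their receptor rose for 4 of 6 (4 when adjusted over the list alone; adjusted p = 1.09e-07). In the IL-1 system 10 of 22 members rose (12 up and 2 down when adjusted over the list alone; adjusted p = 1.09e-07), including Il1b (1.98 ± 0.34), the decoy receptor Il1r2 (2.16 ± 0.20), the alarmin Il33 (1.67 ± 0.27) and the adaptor Myd88 (0.96 ± 0.10).

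Genes of cholesterol synthesis rose together in WT lungs at day 1, 14 of 17 (15 when adjusted over the list alone; adjusted p = 4.83e-07), as with Lss (0.98 ± 0.11) and Cyp51 (0.92 ± 0.15). Injured or transitional epithelium genes rose for 8 of 12 and fell for 1 (adjusted p = 6.64e-08), with the cornified envelope gene Sprr1a at 2.22 ± 0.22, the cell cycle inhibitor Cdkn1a at 1.39 ± 0.18 and the keratin Krt19 at 1.33 ± 0.16. Matrix genes rose for 13 of 34 (16 up and 1 down when adjusted over the list alone; adjusted p = 3.87e-06, adjusted p = 0.0503 with an estimated correlation). Among them were the matrix regulator Thbs1 (1.99 ± 0.24), the collagen cross-linking enzyme Lox (1.57 ± 0.14) and the matrix protein Tnc (1.5 ± 0.27). The fibrillar collagens Col1a1 (0.16 ± 0.27) and Col3a1 (0.33 ± 0.27), and Tgfb1 (0.31 ± 0.22), were not called. NRF2 and oxidative stress genes rose for 6 of 16 (adjusted p = 7.74e-06, adjusted p = 0.0503 with an estimated correlation), among them Gclc, an enzyme of glutathione synthesis (1.01 ± 0.19).

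Weaker list results in WT lungs at day 1 did not pass with an estimated correlation. Type 2 and STAT6 genes rose for 9 of 29 (11 when adjusted over the list alone; adjusted p = 0.00317, adjusted p = 0.214 with an estimated correlation), including Ccl17 (2.18 ± 0.29), Arg1 (2.00 ± 0.44) and the receptor Il4ra (1.21 ± 0.15), while Stat6 itself stood at -0.01 ± 0.09. The call of Arg1 was lost without the arrays of high liver marker score (adjusted p = 0.221), as was that of the neutrophil protein gene S100a8 (adjusted p = 0.0619). Neutrophil markers rose for 8 of 19 and fell for 2 (adjusted p = 0.00163, adjusted p = 0.202 with an estimated correlation), with S100a8 at 1.82 ± 0.41 and the collagenase Mmp8 at 1.40 ± 0.25. Lysosome genes rose for 8 of 20 and fell for 1, and complement genes rose for 4 of 14 and fell for 1 (adjusted p = 0.0164 and 0.0181, both adjusted p = 0.349 with an estimated correlation). T cell markers fell for 8 of 16 (11 when adjusted over the list alone; adjusted p = 0.00332, adjusted p = 0.202 with an estimated correlation), as with Lck (-0.99 ± 0.24) and Cd3g (-0.84 ± 0.19). Interferon response genes fell for 5 of 22 (10 when adjusted over the list alone; adjusted p = 0.00399, adjusted p = 0.202 with an estimated correlation). Markers of alveolar macrophages fell for 4 of 13 (adjusted p = 0.0238), and of eosinophils, mast cells and basophils for 2 of 11 (adjusted p = 0.00255). Markers of NK cells fell for 3 of 11 (adjusted p = 0.0437) and of B cells for 2 of 15 (adjusted p = 0.0497). For these 4 lists the adjusted p with an estimated correlation was 0.338, 0.162, 0.349 and 0.349.

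For WT day 1 exposure the limma test called 4278 of 28173 genes, 2721 up and 1557 down, and 1422 of them changed at least 1.5-fold. Median centring in place of loess called 999, 892 up and 107 down. The count was 5817 with slide as a fixed block. Without the 6 arrays of high liver marker score, which leaves 2 exposed arrays, 2014 were called, and the type 2, lysosome, complement, neutrophil, NK cell and B cell marker lists no longer passed (adjusted p = 0.123, 0.148, 0.213, 0.0932, 0.0768 and 0.0942). With the liver marker score as a covariate the complement, NK cell and B cell lists did not pass (adjusted p = 0.0853, 0.0751 and 0.0853). With median centring in place of loess these 3 (adjusted p = 0.0594, 0.0749 and 0.291) and the NRF2, T cell, interferon and alveolar macrophage lists did not (adjusted p = 0.109, 0.0945, 0.343 and 0.606).

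At day 1 in KO lungs, Il6, Ccl7, Timp1 and Mt2 rose as well, while Cxcl1 and Cxcl5 were not called. Mt2 rose by 3.25 ± 0.30, Il6 by 3.19 ± 0.37, the epidermal growth factor receptor ligand Ereg by 3.09 ± 0.28 and Timp1 by 3.04 ± 0.33 (n = 4 and 5). Has1, a hyaluronan synthase, rose by 2.83 ± 0.36, Ccl7 by 2.79 ± 0.38, Serpina3m by 2.68 ± 0.29 and the peptide hormone gene Cck by 2.58 ± 0.38. Ereg and Cck were near background in the control group, so the size of these 2 rises is uncertain. Saa3 rose by 1.96 ± 0.43, from between -3.85 and -2.46 in controls to between -1.81 and -0.98, and Ccl2 by 1.86 ± 0.31. Cxcl1 stood at 0.59 ± 0.26 (adjusted p = 0.212) and Cxcl5 at 0.14 ± 0.38 (adjusted p = 0.916). Of the 6 largest falls, 5 were genes of liver metabolism or liver hormones, Akr1c6, Cyp2c67, Rgn, Agxt and Hamp2, between -2.65 and -1.67. The liver marker list moved the same way (median -1.83, 0 of 17 members called, 11 down when adjusted over the list alone, fry p = 0.0232, p = 0.101 with an estimated correlation). With the liver marker score as a covariate Rgn was not called (adjusted p = 0.101).

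Acute phase genes rose for 11 of 24 members in KO lungs at day 1 (12 up and 2 down when adjusted over the list alone; adjusted p = 2.21e-05). Cholesterol synthesis genes rose for 12 of 17 (13 when adjusted over the list alone; adjusted p = 2.21e-05) and injured epithelium genes for 7 of 12 (8 when adjusted over the list alone; adjusted p = 6.94e-07). Examples were Lcn2, an iron-siderophore binding protein (1.38 ± 0.19), Cyp51 (0.95 ± 0.16), Sprr1a (2.46 ± 0.23) and the growth factor Areg (2.12 ± 0.38). These 3 lists also passed with an estimated correlation (adjusted p = 0.0378, 0.0374 and 0.0167). NF-kB genes rose for 6 of 23 (10 when adjusted over the list alone; adjusted p = 0.000341, adjusted p = 0.066 with an estimated correlation), with Bcl3 at 1.29 ± 0.25. Monocyte and lymphocyte chemokines rose for 6 of 14 and fell for 1 (adjusted p = 0.00026, adjusted p = 0.066 with an estimated correlation), with Ccl3 at 1.33 ± 0.20. Matrix genes rose for 10 of 34 (13 when adjusted over the list alone; adjusted p = 0.000341, adjusted p = 0.0676 with an estimated correlation), with Thbs1 at 2.24 ± 0.25 and Tnc at 1.68 ± 0.29. The IL-1 system rose for 4 of 22 (9 when adjusted over the list alone; adjusted p = 0.00198, adjusted p = 0.142 with an estimated correlation), with Il33 at 1.76 ± 0.29. Neutrophil chemokines rose for 1 of 6 members and neutrophil markers for 1 of 19, and neither list passed (adjusted p = 0.165 for both).

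In the other lists called in KO lungs at day 1, type 2 and STAT6 genes rose for 7 of 29 (adjusted p = 0.0256), and NRF2 genes for 3 of 16 (adjusted p = 0.021). Lysosome genes rose for 7 of 20 with 1 down, and complement genes for 1 of 14 (both adjusted p = 0.044). Interferon response genes fell for 6 of 22 (adjusted p = 0.0256), with Gbp4 at -1.79 ± 0.38, and T cell markers for 4 of 16 (adjusted p = 0.0212). With an estimated correlation the adjusted p of these 6 lists was 0.281, 0.281, 0.342, 0.342, 0.219 and 0.197. In KO day 1 exposure the interferon, T cell and lysosome lists did not pass with the liver marker score as a covariate (adjusted p = 0.0794, 0.0606 and 0.115). Without the arrays of high score the interferon, lysosome and complement lists did not (adjusted p = 0.0739, 0.104 and 0.225), nor did complement with slide as a block (adjusted p = 0.0525). With median centring in place of loess none of the 6 passed (lowest adjusted p = 0.0647), nor did cholesterol synthesis, NF-kB genes, matrix genes and the IL-1 system (adjusted p = 0.242, 0.267, 0.171 and 0.56). The list means moved in the stated direction on both of the 2 slides that held both groups. The test called 1539 genes, 1166 up and 373 down, of which 538 changed at least 1.5-fold, and with median centring 134, 106 up and 28 down. With slide as a fixed block 3625 were called, and with the liver marker score as a covariate 934. WT and KO lungs shared 951 called rises where 112.6 would be shared by chance, and 244 called falls where 20.61 would be.

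**Figure D1:**
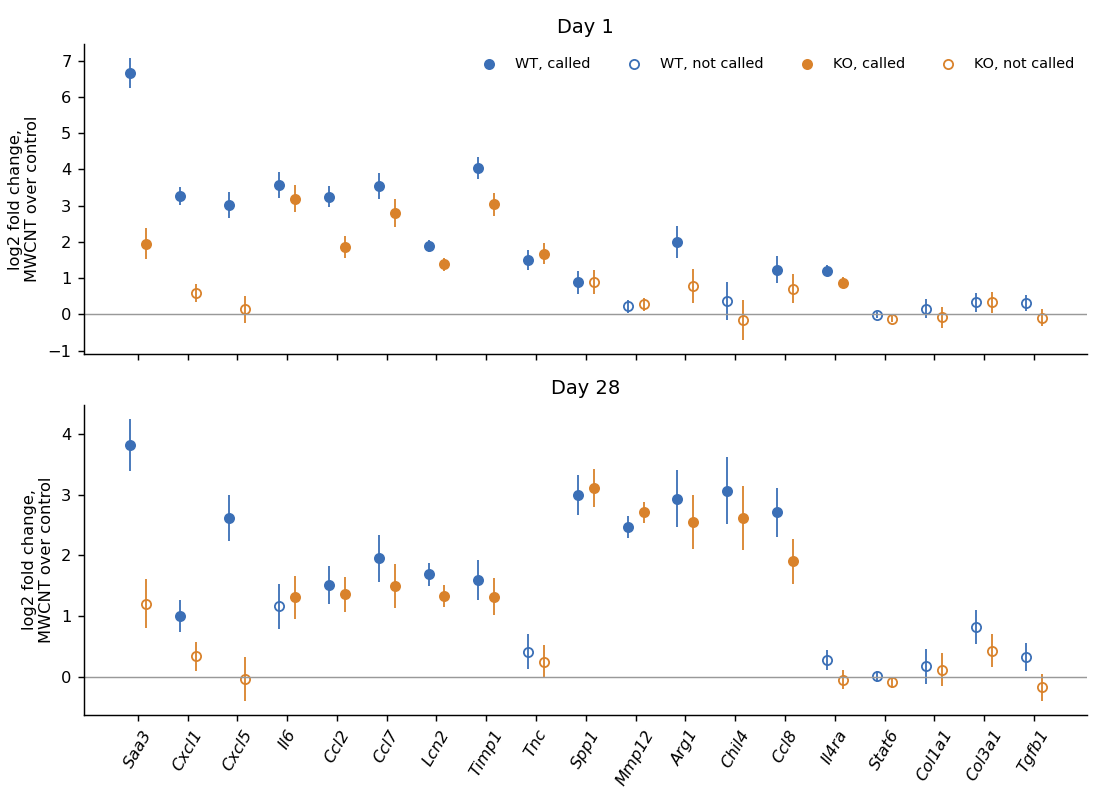
Log2 fold change of exposed over control lungs (y axis) for 19 genes of the fixed panel (x axis) in WT (blue) and KO (orange) at day 1 and day 28, with bars of 1 SE and filled points for called genes. At day 1 Saa3 stood at 6.67 in WT and 1.96 in KO, and at day 28 Spp1 stood at 2.99 and 3.11.

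The genotype difference in day 1 exposure was tested directly, and 21 genes were called, all with a smaller rise or a fall in KO. Saa3 differed by -4.71 ± 0.59 (adjusted p = 4.03e-05), Saa1 by -3.09 ± 0.39 (adjusted p = 4.03e-05), Saa2 by -2.80 ± 0.40 (adjusted p = 0.00026) and Cxcl1 by -2.67 ± 0.36 (adjusted p = 0.000101). Cxcl5 differed by -2.88 ± 0.52 (adjusted p = 0.014) and the acute phase gene Orm3 by -1.19 ± 0.21 (adjusted p = 0.0112). Over the alternatives run for single genes the adjusted p of Saa1 reached at most 0.0187, of Saa3 0.0154 and of Cxcl1 0.0057. That of Saa2 reached 0.142 without the arrays of high liver marker score and 0.051 with the processed intensities. Without KO_1d_MWCNT 2 Cxcl5 and Orm3 were not called (adjusted p = 0.051 and 0.0642), nor was Cxcl5 without KO_1d_control 1 (adjusted p = 0.0508). Over the alternatives run for single genes the adjusted p of Cxcl5 ran from 0.00056 to 0.454 and that of Orm3 from 0.000981 to 0.358. Noxo1, an organizer of the NADPH oxidase, Il1r2 and Hgfac, an activator of hepatocyte growth factor, differed by -1.21 ± 0.23, -1.49 ± 0.29 and -1.25 ± 0.24. The kinase gene Map3k8, named after its values were seen, differed by -0.84 ± 0.17. These 4 lost the call with slide as a block (adjusted p = 0.0533, 0.057, 0.0533 and 0.0563), and the highest adjusted p over the alternatives was 0.641, 0.811, 0.844 and 0.339. They also lost it when single arrays were left out, 8 of the 19 for Noxo1, 10 for Il1r2, 7 for Hgfac and 11 for Map3k8, KO_1d_MWCNT 2 among them each time (adjusted p = 0.0817, 0.0962, 0.0962 and 0.115). Il6 (-0.39 ± 0.51, adjusted p = 0.964), Ccl2 (-1.39 ± 0.42, adjusted p = 0.263), Timp1 (-1.01 ± 0.45, adjusted p = 0.806) and Il1b (-1.08 ± 0.50, adjusted p = 0.831) were not called.

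The other 11 genes of the genotype difference in day 1 exposure, such as Fgg (-5.23 ± 1.09), Hpx (-3.90 ± 0.78), Bhmt2 (-1.79 ± 0.34) and Sgk2 (-1.72 ± 0.31), followed the liver marker score within groups (r from 0.575 to 0.945). None of these 11 was called with that score as a covariate. The division by r was made after the data were seen, and Hgfac came nearest to the 11, at r = 0.449. Of the other 10, Saa1, Saa3, Cxcl1 and Saa2 were called with it (adjusted p = 0.0057, 0.0057, 0.0057 and 0.029), and Cxcl5 was not (adjusted p = 0.354). The acute phase list was lower in KO (5 of 24 members called, 16 when adjusted over the list alone; adjusted p = 0.000155). So were neutrophil chemokines (2 of 6 called, 2 when adjusted over the list alone; adjusted p = 0.00916) and NF-kB genes (0 of 23 called, 7 when adjusted over the list alone; adjusted p = 0.0138). All 3 passed with an estimated correlation (adjusted p = 0.000831, 0.0287 and 0.0287). Of the 5 called acute phase genes, Hpx and Fgg are among the 11 that followed the liver marker score. The liver marker list was lower as well (median -3.42, 0 of 17 called, 16 when adjusted over the list alone, fry p = 0.00109, p = 0.00219 with an estimated correlation). With the liver marker score as a covariate neutrophil chemokines did not pass (adjusted p = 0.103), and without the arrays of high score neither they (adjusted p = 0.1) nor NF-kB genes did (adjusted p = 0.0684). NF-kB genes also failed with median centring in place of loess (adjusted p = 0.376), and acute phase genes passed under all 6 alternatives of the list test (adjusted p from 4.83e-30 to 0.034). The count of 21 ranged from 4 without KO_1d_MWCNT 2 to 204 without WT_1d_MWCNT 2, and was 11 with slide as a fixed block.

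**Figure D2:**
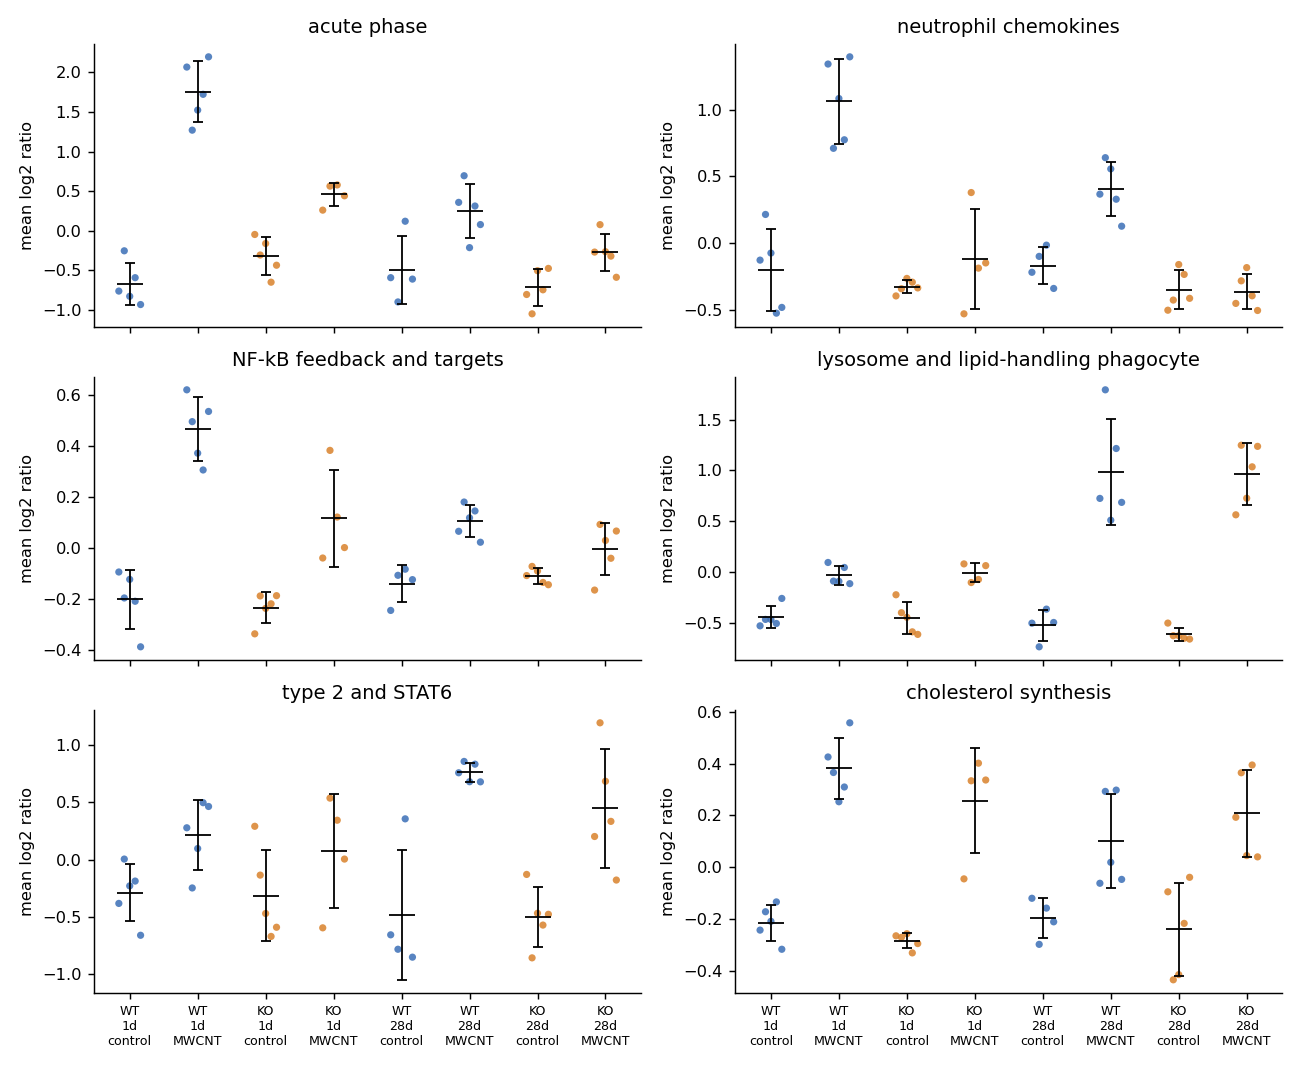
Mean log2 ratio of the members of 6 gene lists (y axis) on each array (points) by group (x axis), each gene centred on its mean over all arrays. Lines give the group mean and SD, with WT in blue and KO in orange. The mean difference between exposed and control lungs in the lysosome list was 1.51 in WT and 1.57 in KO at day 28.

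**Figure D3:**
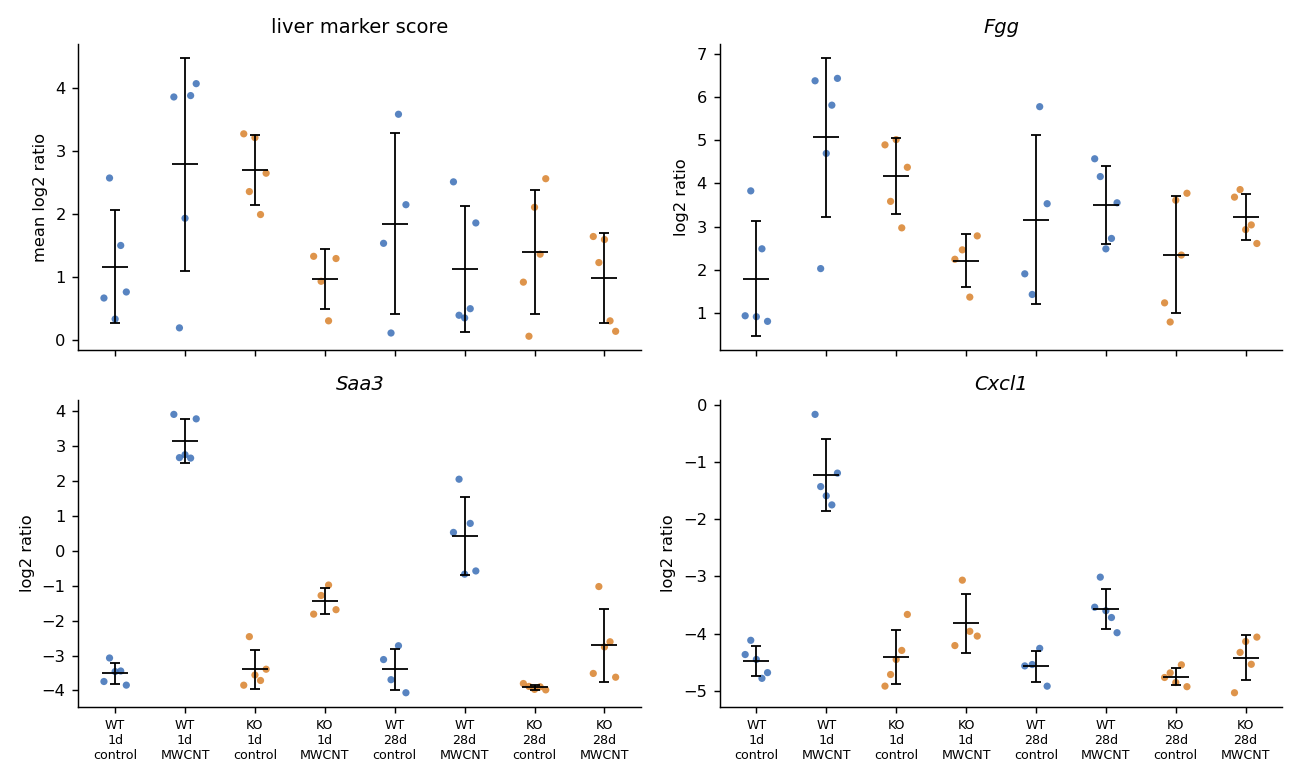
Liver marker score and the log2 ratios of Fgg, Saa3 and Cxcl1 (y axes) on each array (points) by group (x axis), with the group mean and SD as lines. At day 1 Saa3 lay between 2.66 and 3.91 in WT exposed lungs and between -1.81 and -0.98 in KO exposed lungs.

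At day 28 in WT lungs, genes of lipid-laden and lysosome-rich macrophages, macrophage chemokines and several genes induced by IL-4 and IL-13 were higher than in controls. Gpnmb, a glycoprotein of phagocytes with active lysosomes, rose by 3.84 ± 0.32 (14.3-fold, n = 5 and 4), the macrophage lipid receptor Trem2 by 3.12 ± 0.29, Wfdc17 by 3.07 ± 0.35 and the anion exchanger Slc26a4 by 3.56 ± 0.56. Saa3 rose by 3.82 ± 0.43. The chitinase-like Chil4 rose by 3.07 ± 0.56, osteopontin, encoded by Spp1, by 2.99 ± 0.33, Arg1 by 2.94 ± 0.47, the chemokine Ccl8 by 2.71 ± 0.40 and the macrophage elastase Mmp12, near background in controls, by 2.48 ± 0.18. Cxcl5 rose by 2.62 ± 0.38. Fxyd4 rose by 3.29 ± 0.38 but was not called with the processed intensities (adjusted p = 0.26; 1.58e-08 at the lowest under other alternatives). The goblet cell gene Clca1 had the largest estimate, 5.53 ± 1.48 (adjusted p = 0.0335), and lost its call when any of 7 arrays was left out, among them WT_28d_control 1 (adjusted p = 0.151) and WT_28d_control 4 (adjusted p = 0.169; 0.00076 at the lowest under other alternatives). The largest fall was that of Asgr1, a liver lectin (-1.55 ± 0.37), not called without WT_28d_MWCNT 2 (adjusted p = 0.072) or WT_28d_MWCNT 4 (adjusted p = 0.0515). The endothelial gene Esm1 followed (-1.38 ± 0.31), not called without WT_28d_control 4 (adjusted p = 0.0866) or with median centring in place of loess (adjusted p = 0.199). Entpd8 fell by 1.02 ± 0.21, not called with the processed intensities (adjusted p = 0.0816), and the falls of Pon1, Gsta2 and Colq were lost without WT_28d_MWCNT 2 (adjusted p = 0.234, 0.168 and 0.127), among other arrays.

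The lysosome list rose for 15 of 20 members in WT lungs at day 28 (19 when adjusted over the list alone; adjusted p = 1.59e-08), among them the protease Ctsk (2.05 ± 0.18) and the proton pump subunit Atp6v0d2 (1.98 ± 0.27). Monocyte and interstitial macrophage markers rose for 8 of 16 (8 when adjusted over the list alone; adjusted p = 1.03e-07), as with Ms4a7 (2.39 ± 0.24), Cd14 (1.27 ± 0.22) and Adgre1 (1.20 ± 0.19). Chemokines of monocytes and lymphocytes rose for 6 of 14 (9 when adjusted over the list alone; adjusted p = 4.02e-06), with Ccl9 at 2.70 ± 0.28 and Ccl7 at 1.95 ± 0.38. Complement genes rose for 8 of 14 (10 when adjusted over the list alone; adjusted p = 4.13e-06), with C3 at 1.52 ± 0.21 and C3ar1 at 1.11 ± 0.16. Acute phase genes rose for 9 of 24 (13 when adjusted over the list alone; adjusted p = 0.000103), with Saa1 at 1.73 ± 0.28 and Lcn2 at 1.69 ± 0.19. Type 2 and STAT6 genes rose for 9 of 29 (15 when adjusted over the list alone; adjusted p = 0.000103), while Il13 and Stat6 stood at 0.16 ± 0.13, near background, and 0.01 ± 0.09. These 6 lists passed with an estimated correlation (adjusted p from 0.000254 to 0.00852), and each was higher on 4 of 4 slides.

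For WT day 28 exposure matrix genes rose for 3 of 34 members (7 up and 3 down when adjusted over the list alone; adjusted p = 0.0427, adjusted p = 0.269 with an estimated correlation). With slide as a block or the liver marker score as a covariate the list did not pass (adjusted p = 0.0661 and 0.0671). Col1a1 (0.17 ± 0.28), Col3a1 (0.82 ± 0.28), Tnc (0.41 ± 0.29) and Tgfb1 (0.33 ± 0.23) were not called. NF-kB genes rose for 3 of 23 (9 when adjusted over the list alone; adjusted p = 0.0068). Neutrophil chemokines rose for 2 of 6 (3 up and 1 down when adjusted over the list alone; adjusted p = 0.00998) and the IL-1 system for 3 of 22 (adjusted p = 0.0127). Cholesterol synthesis rose for 2 of 17 (10 when adjusted over the list alone; adjusted p = 0.0205). Alveolar type 2 markers rose for 1 of 13 (adjusted p = 0.0244) and injured epithelium for 2 of 12 (adjusted p = 0.0259). With an estimated correlation the adjusted p of these 6 lists was 0.0741, 0.115, 0.101, 0.115, 0.115 and 0.123, and without the arrays of high liver marker score injured epithelium did not pass (adjusted p = 0.0635). With median centring in place of loess matrix genes and 5 of these 6, all but neutrophil chemokines, did not pass (lowest adjusted p = 0.522). The test called 699 genes, 580 up and 119 down, and 464 changed at least 1.5-fold. It called 138 with median centring, 133 up and 5 down. The count was 944 with slide as a fixed block, 313 without WT_28d_MWCNT 2, and 241 when only the WT day 28 arrays were fitted.

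At day 28 in KO lungs the largest rises were in many of the same genes. Gpnmb rose by 4.05 ± 0.30 (n = 5 and 5), Trem2 by 3.34 ± 0.28, and Slc26a4 by 3.19 ± 0.53. The neuropeptide gene Npy rose by 3.13 ± 0.18 and Spp1 by 3.11 ± 0.31, Wfdc17 by 2.82 ± 0.33 and Mmp12 by 2.71 ± 0.17. Npy and Mmp12 were near background in controls, so the size of their rises is uncertain. Chil4 rose by 2.62 ± 0.52, Arg1 by 2.55 ± 0.44, Ccl8 by 1.90 ± 0.38 and Chil3, another chitinase-like protein, by 1.84 ± 0.38. Clca1 stood at 4.43 ± 1.40 (adjusted p = 0.0896), Saa3 at 1.21 ± 0.41 (adjusted p = 0.122) and Cxcl5 at -0.04 ± 0.36 (adjusted p = 0.987). The vasodilator peptide gene Adm (-1.06 ± 0.20), the neuropeptide gene Gal (-1.0 ± 0.17) and Igfbp3, a carrier of insulin-like growth factors (-0.97 ± 0.18), fell.

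The lysosome list rose for 17 of 20 members in KO lungs at day 28 (18 when adjusted over the list alone; adjusted p = 1.62e-09), with Atp6v0d2 at 2.18 ± 0.25 and Ctsk at 2.11 ± 0.17. Monocyte and interstitial macrophage markers rose for 7 of 16 (9 when adjusted over the list alone; adjusted p = 3.43e-07). Monocyte and lymphocyte chemokines rose for 8 of 14 with 1 down (10 up and 1 down when adjusted over the list alone; adjusted p = 7.08e-06). Cholesterol synthesis genes rose for 8 of 17 (14 when adjusted over the list alone; adjusted p = 0.000167), and complement genes for 6 of 14 (7 when adjusted over the list alone; adjusted p = 0.000167). Examples were Ms4a7 (2.29 ± 0.23), Ccl9 (2.56 ± 0.26), Idi1 (0.82 ± 0.14) and C3ar1 (1.07 ± 0.15). These 5 lists passed with an estimated correlation (adjusted p from 0.000104 to 0.0126) and were higher on 5 of 5 slides. Type 2 and STAT6 genes rose for 7 of 29 (14 up and 1 down when adjusted over the list alone; adjusted p = 0.00416, adjusted p = 0.0755 with an estimated correlation). The IL-1 system rose for 5 of 22 (adjusted p = 0.00416, adjusted p = 0.0771 with an estimated correlation), with Il33 at 1.87 ± 0.27 and the inflammasome adaptor Pycard at 0.67 ± 0.14.

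Lower in the ranking of KO lungs at day 28, acute phase genes rose for 6 of 24 (9 when adjusted over the list alone; adjusted p = 0.0189). Alveolar type 2 markers rose for 1 of 13 (adjusted p = 0.0227) and injured epithelium for 1 of 12 (adjusted p = 0.0313). Matrix genes rose for 4 of 34 (7 up and 1 down when adjusted over the list alone; adjusted p = 0.0381). NRF2 genes rose for 4 of 16 (5 up and 3 down when adjusted over the list alone; adjusted p = 0.0418). The NRF2 list had a median of -0.04 and a mean of 0.07, so its median and its test differ in sign. With an estimated correlation the adjusted p of these 5 lists was 0.14, 0.14, 0.182, 0.302 and 0.296. In KO day 28 exposure matrix genes did not pass with the liver marker score as a covariate (adjusted p = 0.0508), nor did they (adjusted p = 0.0632) or injured epithelium (adjusted p = 0.063) without the arrays of high score. None of the 5 passed with median centring in place of loess (lowest adjusted p = 0.404), nor did complement, cholesterol synthesis and the IL-1 system (adjusted p = 0.235, 0.43 and 0.572). Neutrophil chemokines were called for 0 of 6 members and did not pass (median 0.07, mean -0.02, adjusted p = 0.799). The test called 729 genes, 568 up and 161 down, and 411 changed at least 1.5-fold. It called 132 with median centring, 124 up and 8 down. With slide as a fixed block the count was 1357, and without KO_28d_MWCNT 2 it was 412.

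No gene passed the limma test of the genotype difference at day 28, where 844 of 28173 genes had an unadjusted p under 0.05. The 3 of smallest p were Cxcl5 (-2.66 ± 0.52, adjusted p = 0.33), Noxo1 (-1.11 ± 0.23, adjusted p = 0.446) and Saa3 (-2.62 ± 0.59, adjusted p = 0.813). Without KO_28d_MWCNT 2 the count was 2, and without the arrays of high liver marker score it was 4. None of the 31 lists passed with fry, while camera with a preset correlation passed 10 and with an estimated correlation 0. WT and KO lungs shared 356 called rises at day 28 where 11.69 would be shared by chance, and 27 falls where 0.68 would be. Across the 1045 genes called in either genotype the log2 fold changes correlated at r = 0.901, and across 4621 at day 1 at r = 0.629. These correlations are across genes, which are not independent replicates, and the genes were chosen by their call, at day 1 mostly in WT.

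Lists of other lung compartments did not pass in the 4 exposure comparisons. In the order WT day 1, KO day 1, WT day 28 and KO day 28, the adjusted p was 0.886, 0.721, 0.444 and 0.148 for cell cycle genes, 0.0872, 0.165, 0.32 and 0.61 for dendritic cells, and 0.219, 0.165, 0.723 and 0.302 for alveolar type 1 cells. It was 0.179, 0.763, 0.943 and 0.34 for club and ciliated cells, and 0.317, 0.792, 0.347 and 0.0544 for endothelium. For fibroblasts with smooth muscle it was 0.886, 0.69, 0.262 and 0.0664, and for cardiac muscle 0.317, 0.588, 0.639 and 0.799. It was 0.803, 0.792, 0.154 and 0.11 for blood cells, and 0.96, 0.821, 0.919 and 0.73 for adipose tissue. With slide as a block dendritic cell markers were lower in WT day 1 exposure (adjusted p = 0.00267) and KO day 1 exposure (adjusted p = 0.0149), where the circadian clock list was lower as well (adjusted p = 0.0439). Alveolar macrophage markers were higher in WT day 28 exposure (adjusted p = 0.0449). Also with slide as a block, endothelial markers (adjusted p = 0.0236) and fibroblast and smooth muscle markers (adjusted p = 0.0318) were lower in KO day 28 exposure. Club and ciliated cell markers were lower in WT day 1 exposure with the liver marker score as a covariate (adjusted p = 0.0245), and with it NRF2 genes were higher in WT day 28 exposure (adjusted p = 0.0219).

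**Figure D4:**
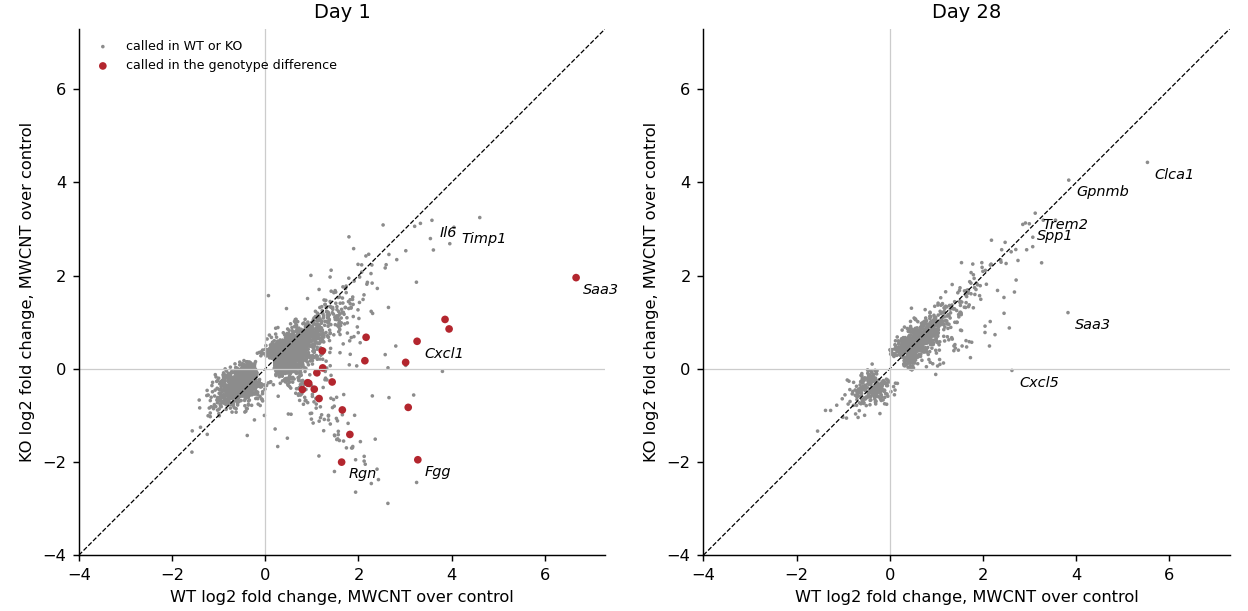
Log2 fold change of exposed over control lungs in KO (y axis) against WT (x axis) for genes called in either genotype, 4621 at day 1 and 1045 at day 28, with the line of equal change dashed. The 21 genes of the day 1 genotype difference, in red, lie below the line.

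The exposure effect differed between day 28 and day 1 for 1481 genes in WT lungs, 497 with a higher and 984 with a lower value at day 28 (107 with median centring, 21 higher and 86 lower). Among the 10 of smallest p, Npy (2.89 ± 0.26) and Mmp12 (2.26 ± 0.25) had the higher effect at day 28, and Serpina3m (-4.14 ± 0.39), Saa2 (-3.21 ± 0.40), the aggrecan-cleaving protease gene Adamts4 (-2.56 ± 0.28) and the transcription factor Cebpd (-2.20 ± 0.23) the lower. Npy and Mmp12 were near background in controls of both days and after exposure at day 1, so the size of these 2 differences is uncertain. The acute phase list was lower for 13 of 24 members (17 when adjusted over the list alone; adjusted p = 2.43e-05, adjusted p = 0.0327 with an estimated correlation), and NF-kB genes were lower for 5 of 23 (adjusted p = 0.00153). Lysosome genes were higher for 9 of 20 (12 when adjusted over the list alone; adjusted p = 0.00153), with Trem2 at 2.82 ± 0.40. Monocyte and interstitial macrophage markers were higher for 5 of 16 and lower for 1 (adjusted p = 0.00153), with Ms4a7 at 2.55 ± 0.33. These last 3 lists had an adjusted p of 0.104 with an estimated correlation. The liver marker list was also lower at day 28 (median -2.17, fry p = 0.0145, p = 0.0984 with an estimated correlation).

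Smaller shifts between the days in WT lungs were called for injured epithelium (4 of 12 lower and 1 higher, adjusted p = 0.0117) and alveolar macrophage markers (2 of 13 higher, adjusted p = 0.0126). The same was so for eosinophil, mast cell and basophil markers (0 of 11 called by limma, list higher, adjusted p = 0.0124) and the IL-1 system (4 of 22 lower and 1 higher, adjusted p = 0.0314). Neutrophil chemokines (2 of 6 lower, adjusted p = 0.0314), complement (3 of 14 higher, adjusted p = 0.0406) and cholesterol synthesis (3 of 17 lower, adjusted p = 0.049) followed. None of these passed with an estimated correlation (adjusted p from 0.164 to 0.325). For the time difference in WT exposure the IL-1 system, neutrophil chemokines and cholesterol synthesis did not pass with the liver marker score as a covariate (adjusted p = 0.0715, 0.0892 and 0.0892). Without the arrays of high score these 3 (adjusted p = 0.171, 0.24 and 0.266) and injured epithelium (adjusted p = 0.0693) did not, and with slide as a block neutrophil chemokines did not (adjusted p = 0.056). With slide as a block T cell, dendritic cell and alveolar type 2 markers were higher and matrix genes lower at day 28 (adjusted p = 0.0389, 0.00165, 0.0264 and 0.0339). With median centring in place of loess acute phase genes, neutrophil chemokines and eosinophil, mast cell and basophil markers were the 3 lists that passed.

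In KO lungs 274 genes differed between the days, 141 higher and 133 lower at day 28 (21 with median centring, 13 higher and 8 lower). Npy (3.07 ± 0.26), Trem2 (2.94 ± 0.40), Bcan (2.66 ± 0.38), Mmp12 (2.44 ± 0.25), Ms4a7 (2.35 ± 0.33) and Zranb3 (2.18 ± 0.27) had the higher effect at day 28. Adamts4 (-2.07 ± 0.28), Foxs1 (-0.96 ± 0.14) and the small GTPase Rras2 (-0.92 ± 0.12) had the lower. Npy and Mmp12 were near background in the same groups as in WT. Lysosome genes were higher for 7 of 20 (13 when adjusted over the list alone; adjusted p = 0.00105, adjusted p = 0.0259 with an estimated correlation). So were monocyte and interstitial macrophage markers for 4 of 16 (adjusted p = 0.00433, adjusted p = 0.0529 with an estimated correlation). Interferon response genes were higher for 4 of 22 (14 when adjusted over the list alone; adjusted p = 0.0134, adjusted p = 0.0878 with an estimated correlation). Injured epithelium genes were lower for 4 of 12 (7 when adjusted over the list alone; adjusted p = 0.0134, adjusted p = 0.117 with an estimated correlation). None of these 4 lists passed with median centring in place of loess for the time difference in KO exposure (lowest adjusted p = 0.542), and with the liver marker score as a covariate acute phase genes were lower (adjusted p = 0.0409). The count was 161 without KO_1d_MWCNT 3. The counts were 2347 in WT and 616 in KO with slide as a fixed block.

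Unexposed KO and WT lungs differed in few genes. At day 1, 8 of 28173 were called, 4 higher and 4 lower in KO (n = 5 and 5), and at day 28, 5 were called, 2 higher and 3 lower (n = 5 and 4). The counts were 14 and 8 with slide as a fixed block. Kansl1l, which encodes a protein related to a histone acetyltransferase subunit, was lower in KO by -1.33 ± 0.17 and -1.21 ± 0.17 at the 2 days. Lancl1, a glutathione-binding protein, was lower by -0.75 ± 0.09 and -0.71 ± 0.09, and Poglut2, an O-glucosyltransferase of the endoplasmic reticulum, by -0.63 ± 0.08 and -0.67 ± 0.08. Poglut2 was not called with Cy5 alone (adjusted p = 0.0902 at day 1 and 0.0824 at day 28) or with median centring in place of loess (adjusted p = 0.387 and 1). With median centring Kansl1l and Lancl1 were also not called (adjusted p = 0.387 and 0.47 at day 1, 1 for both at day 28). An unnamed transcript on chromosome 1 from 58443698 to 58449898 (build mm9, per the identifiers in the files) was higher in KO by 0.84 ± 0.12 and 0.88 ± 0.12. A further one from 58440355 to 58449627 was called at day 1 (0.80 ± 0.15). The neuropilin gene Nrp2 was called at day 1 (0.64 ± 0.11), but not without KO_1d_control 1, KO_1d_control 4 or WT_1d_control 5 (adjusted p = 0.0613, 0.0523 and 0.0611). The microtubule gene Map2 was called at day 28 (1.13 ± 0.17, adjusted p = 0.00114), but not with the processed intensities (adjusted p = 0.503).

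Among clock genes, Dbp was higher (1.45 ± 0.23, adjusted p = 0.00223) and Arntl lower (-1.02 ± 0.18, adjusted p = 0.014) in KO controls at day 1. With median centring in place of loess Arntl was not called (adjusted p = 0.387). It also lost its call without any of 5 arrays, KO_1d_control 1, 3 or 4 or WT_1d_control 1 or 5 (adjusted p = 0.0837, 0.0608, 0.0523, 0.0902 and 0.0703). The circadian clock list was higher (1 of 14 up and 1 down, 9 up and 2 down when adjusted over the list alone; adjusted p = 0.0159, adjusted p = 0.0389 with an estimated correlation). In the same comparison the liver marker list was higher (median 1.53, 0 of 17 called, 11 when adjusted over the list alone, fry p = 0.0287, p = 0.0302 with an estimated correlation). With its score as a covariate the clock list did not pass (adjusted p = 0.0859). At day 28 no list differed between control genotypes (lowest adjusted p = 0.582), and Dbp stood at 0.96 ± 0.25 (adjusted p = 0.853).

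**Figure D5:**
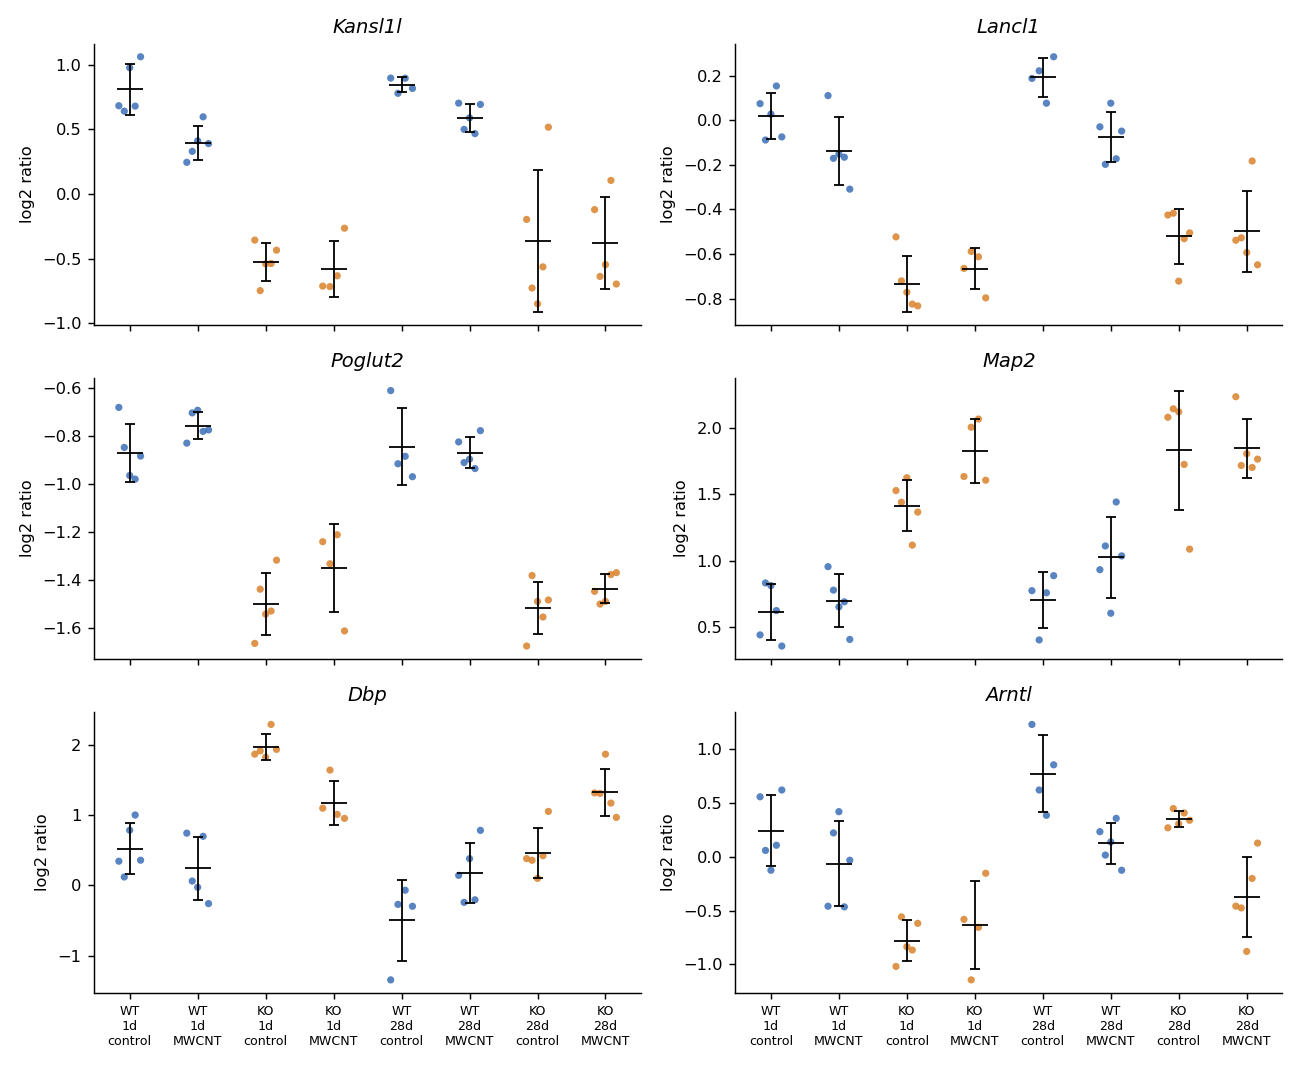
Log2 ratio of 6 genes (y axes) on each array (points) by group (x axis), with the group mean and SD as lines, WT in blue and KO in orange. The 19 KO and 19 WT arrays do not overlap for Poglut2, with a gap of 0.232 on the log2 scale.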

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

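The tests of liver RNA, slide, exchanged labels, chromosome and other probes, and the counts over 100 random splits of the samples, were chosen after the result was seen, and the test of time of day before.

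In the day 1 genotype difference, 21 genes were called. In 100 splits of the samples the real one gave 21 of the 28096 genes in that test, and 2 splits were as large, the real one included. The highest other gave 77, so a wrong labelling gave more genes and the count alone does not exclude chance. The split with 77 exchanged WT_1d_MWCNT 2 and KO_1d_MWCNT 2, and leaving these arrays out gave the highest and the lowest count (204 and 4). Leaving out WT_1d_MWCNT 3, WT_1d_control 2 or KO_1d_control 4 gave 142, 95 and 68, so the count rests on several arrays. Within its group the liver marker score was lowest in WT_1d_MWCNT 2 (0.196) and KO_1d_control 4 (1.99) and highest in WT_1d_control 2 (2.57). That of KO_1d_MWCNT 2 (0.934) lay inside its group. A split with several times the real count points to a structure of the samples, and it kept the other 17 arrays in their groups. No cause of it was tested. The genes were Saa3 (-4.71), Saa1 (-3.09), Cxcl5 (-2.88), Saa2 (-2.80), Cxcl1 (-2.67), Il1r2 (-1.49), Hgfac (-1.25), Noxo1 (-1.21), Orm3 (-1.19) and Map3k8 (-0.84), and the liver-linked Fgg (-5.23), Hpx (-3.90), Rgn (-3.64), Hpd (-3.22), Creb3l3 (-2.54), Mat1a (-1.96), Bhmt2 (-1.79), Sgk2 (-1.72), Gm4952 (-1.49), Smlr1 (-1.24) and Slc25a47 (-1.21). The list means differed by -1.65 for acute phase genes, -1.06 for neutrophil chemokines and -0.32 for NF-kB genes.

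RNA of liver in the lung samples is a candidate explanation for the 11 genes that follow the liver marker score within groups. The 17 liver markers, none of them called, were all lower in this difference (median -3.42, from -6.24 to -0.89). In day 1 controls, where the liver marker list was higher in KO (median 1.53), all 11 were higher in KO as well (median 0.85). Of the 10 called genes that do not follow the score, 8 were also higher in KO controls (median 0.115). These controls are part of the difference by which the genes were called, so the selection favours higher KO controls. The values in controls are therefore no separate support for liver RNA. The markers share no gene with the 31 fixed lists, and the albumin gene Alb, looked up after the data were seen, stood at -3.57 ± 1.32 (adjusted p = 0.559). An effect of the genotype on these genes in the lung stays open as untested.

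With the liver score as a covariate 5 of all 21 genes kept over 50% of their difference by more than 2 SE. For these 5 genes this argues against liver RNA in proportion to the score as the whole cause. They were Saa3 (-4.39 ± 0.70), Saa1 (-2.82 ± 0.46), Cxcl1 (-2.63 ± 0.43) and Saa2 (-2.59 ± 0.47), which were still called, and Map3k8 (-0.84 ± 0.17 before, -0.98 ± 0.20 with the covariate), which was not (adjusted p = 0.158). Its difference and SE grew alike, and its adjusted p rose as fewer genes, 4 in place of 21, were called in the same test. Without the arrays of high score Saa3, Saa1 and Cxcl1 were still called (adjusted p = 0.0154, 0.0187 and 0.00462) and Saa2 was not (0.142). For the 5 other genes that do not follow the score, liver RNA as a cause stays open, since the share left less 2 SE was at most 45.9%. Their calls ended with smaller differences and larger SE: Cxcl5 went from -2.88 ± 0.52 to -2.31 ± 0.59, Il1r2 from -1.49 ± 0.29 to -1.38 ± 0.35, Noxo1 from -1.21 ± 0.23 to -1.06 ± 0.27, Orm3 from -1.19 ± 0.21 to -1.03 ± 0.25 and Hgfac from -1.25 ± 0.24 to -0.86 ± 0.26. In day 1 controls Hgfac was higher in KO by 0.74 ± 0.16, as the liver markers were. These controls are part of the difference by which Hgfac was called, so this is no separate support for liver RNA. For the 10 genes that do not follow the score the tables argue against slide (a median of 95.0% left with slide as a block). Exchanged genotype labels at day 1 are argued against by the 5 features called in day 28 controls. On these, 0 of the 19 day 1 arrays lay on the side of the other genotype. The features cannot show an exchange of exposed and control labels, or of days, within a genotype. A weaker induction without IL-1 receptor signalling may explain Saa1, Saa3 and Cxcl1, as a hypothesis found and tested on the same data. Whether such a weaker induction extends to neutrophil chemokines as a list stays open. That list was lower in KO in the main fit and did not pass with the liver marker score as a covariate.

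Genes that differ between unexposed KO and WT lungs lay mostly on chromosome 1, where Il1r1 lies. Of 9 called features 7 were on that chromosome, and of the 7 with a gene name 5, against 982 of 17125 tested genes (5.73%, Fisher exact p = 1.2e-05). DNA of another strain kept around the targeted gene may explain this. The tested genes between each and Il1r1 number 18 for Poglut2, 102 for Nrp2, 122 for Map2, 125 for Kansl1l and 128 for Lancl1. A sequence variant under the probe is argued against as the whole cause for 2 genes whose other probe moved the same way, Map2 at both days (0.50 and 0.83, the probe used 0.80 and 1.13) and Kansl1l at day 1 (-0.40, the probe used -1.33). At day 28 the other probe of Kansl1l stood at -0.17 ± 0.11 (the probe used -1.21), so a variant that adds to its size stays open. For 1 gene, Lancl1, the other probe moved the opposite way (0.31 ± 0.08 at day 1, 0.36 ± 0.09 at day 28), which a variant under the used probe alone would not give. For 2 genes, Nrp2 (0.19 ± 0.19 and 0.10 ± 0.20) and Poglut2 (0.07 ± 0.09 and 0.07 ± 0.09), the other probe stayed within about 1 SE of 0. A variant under the used probe would give this. These 2 genes were grouped by that very result, so it does not test a variant, which stays open for them. In 100 splits no other split gave as many genes at either day (8 genes with 1 in the highest other split at day 1, 5 with 3 at day 28). This argues against chance as far as 100 splits can, and at day 28 by a small margin.

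Dbp was higher and Arntl lower in KO controls at day 1. The directions were the same in day 28 controls (0.96 ± 0.246 and -0.418 ± 0.196), where neither gene was called. Between exposed KO and WT lungs Dbp and Arntl stood at 0.935 ± 0.246 and -0.57 ± 0.196 at day 1. At day 28 these values were 1.157 ± 0.232 and -0.501 ± 0.185. Over 38 arrays the 2 genes moved oppositely within groups (Pearson r = -0.675, permutation p = 9e-05; Spearman rho = -0.625, permutation p = 0.00041; r = -0.633 without the 2 arrays farthest from the median of Dbp), as a shift of clock phase would give. A different hour of collection and an effect of the genotype on the clock cannot be told apart, since the labels give no hour.

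The exposure effect differed between the days for 1481 genes in WT and 274 in KO. In 100 splits WT gave 1472 and the highest other 2, which argues against chance. In KO the real split gave 273 and the highest other 641, with 4 of 100 splits as large, the real one included. Wrong labellings gave more genes there, so the count alone does not exclude chance. The larger counts came from exchanges among controls of the 2 days, which points to a structure of the samples. Npy and Mmp12 were near background in all groups but the exposed ones at day 28, so the size of their differences is uncertain. In WT the genes of smallest p were Npy (2.89), Serpina3m (-4.14), Ifrd1 (-1.37), Cebpd (-2.20), Adamts4 (-2.56), Mmp12 (2.26), Tmem37 (-1.49), Cltb (-1.15), Mirt2 (-1.85) and Saa2 (-3.21). In KO they included Npy (3.07), Mmp12 (2.44), Zranb3 (2.18), Rras2 (-0.92), Adamts4 (-2.07), Trem2 (2.94), Ms4a7 (2.35), Bcan (2.66) and Foxs1 (-0.96). List means in WT differed by -1.69 for acute phase, -0.69 for neutrophil chemokines, -0.24 for the IL-1 system, -0.42 for NF-kB, 1.09 for lysosome, -0.30 for cholesterol synthesis, 0.38 for complement, 0.53 for alveolar macrophages, 0.57 for monocytes and interstitial macrophages, 0.36 for eosinophils with mast cells and basophils, and -0.47 for injured epithelium. In KO they differed by 0.70 for interferon response, 1.13 for lysosome, 0.57 for monocytes and interstitial macrophages, and -0.51 for injured epithelium.

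For the exposure comparisons other than WT day 28, no other of 100 splits each gave as many genes, which argues against chance. WT day 1 gave 4272 genes (highest other 2698), KO day 1 1536 (482) and KO day 28 727 (48). WT day 28 gave 697, and another split gave 752, with the controls and WT_28d_MWCNT 3 on one side and the other 4 exposed arrays on the other. There 2 of 100 splits were as large, the real one included, so the count alone does not exclude chance. For the day 28 genotype difference the real split gave 0, so all 100 splits are as large and decide nothing; the highest other gave 43.

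Single arrays lay far from the others of their group in 23 of 280 groups tested, where chance gives about 1 in 20 (5 percent). Probes well above background numbered about 29950 for WT_28d_MWCNT 2 (the others 32670 to 33580) and about 44280 for KO_28d_MWCNT 5 (31900 to 35090). The median correlation with the own group was 0.892 for WT_1d_control 5 (0.958 to 0.966) and 0.962 for KO_1d_MWCNT 3 (0.952 to 0.953). Il1r1 stood at 0.008 in WT_28d_control 1 (0.40 to 0.46). Among list means, WT_1d_control 5 was apart for interferon response (-0.62), lysosome (-0.26), alveolar type 2 (-0.17) and endothelial markers (-0.028), WT_1d_control 2 for injured epithelium (-0.14) and fibroblasts (0.69), and KO_28d_MWCNT 2 for B and plasma cells (0.79) and injured epithelium (0.59). WT_28d_control 3 was apart for type 2 genes (0.36, the others -0.85 to -0.66), WT_1d_MWCNT 1 for NRF2 (0.048), KO_28d_control 1 for lysosome (-0.50), KO_1d_MWCNT 1 for cholesterol synthesis (-0.045), KO_28d_control 5 for neutrophil markers (-0.57) and KO_1d_control 2 for T cells (0.29). WT_1d_MWCNT 5 was apart for B and plasma cells (0.041) and blood cells (0.36), KO_1d_MWCNT 4 for fibroblasts (-0.36) and WT_1d_MWCNT 4 for adipose markers (3.99, the others -0.50 to -0.01).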

How the results depend on the processing

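The alternatives with the liver marker score as a covariate, without the 6 arrays of high score (which leaves 2 WT_1d_MWCNT arrays), and with the deposited log2 table for single genes were chosen after the data were seen. Of 684 results for named genes none changed sign in any alternative run where the main fit or the alternative called the gene. A change of sign with no call in either fit was not counted. With the processed intensities 68 lost their call, with median centring 243, with Cy5 alone 48 and with slide as a fixed block 10. With the deposited log2 values 22 lost it, with the liver covariate 63 and without the high-score arrays 112. In the same order 2, 1, 6, 13, 2, 7 and 9 gained one. Over 8733 results with single arrays left out 720 lost and 19 gained a call. The quantile step on average intensity leaves log ratios as they are, and Il1r1 has 1 probe, so these 2 alternatives could change nothing. Median in place of mean signals, named beforehand, was not run, since the median signals had to be used.

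The counts of called genes kept within 1.5 times except as follows; the cause was not tested unless given. Median centring, which removes no trend with intensity, gave 999 genes in WT and 134 in KO at day 1, and 138 and 132 at day 28. It gave 9 for the day 1 genotype difference, 4 and 2 for controls at day 1 and 28, and 107 and 21 for the time difference in WT and KO. With it the median of all genes was -0.14 in the day 1 genotype difference (0.01 with loess) and 0.22 in day 1 controls (about 0 with loess). A fold minimum of 1.5 drops small changes by construction and gave 1422, 538, 464 and 411. Slide as a fixed block gave 3625 for KO day 1, 1357 for KO day 28, 11 for the day 1 genotype difference, 14 and 8 for the controls, and 2347 and 616 for the time difference. Slide as a random block (correlation 0.199) gave 2762 for KO day 1, 1085 and 1283 at day 28, 134 for the day 1 genotype difference, 8 for day 28 controls, and 2373 and 544 for the time difference. A fit to the groups of the comparison alone, with fewer samples to estimate the spread, gave 2275 for WT day 1, 241 for WT day 28, 5 for the day 1 genotype difference, 4 and 0 for the controls (limma), and 935 for the time difference in WT.

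The liver covariate gave 934 for KO day 1, 4 for the day 1 genotype difference and 5 for day 1 controls. Without the high-score arrays the counts were 2014 and 1018 at day 1, 3 and 4 for the genotype difference at day 1 and 28, 5 for day 1 controls and 146 for the time difference in KO. The 4 genes at day 28 were Cxcl5, Ly6i, Noxo1 and Ly6f. For the day 1 genotype difference the processed intensities gave 13, Cy5 alone 61, no filter on dim probes 13, a filter on all arrays 5, each probe on its own 11 and the deposited log2 values 45, and for day 28 controls the mean of all probes gave 3.

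With single arrays left out the counts ran from 3000 to 4564 in WT and 1030 to 1505 in KO at day 1. At day 28 they ran from 313 (without WT_28d_MWCNT 2) to 928 in WT and 412 (without KO_28d_MWCNT 2) to 792 in KO. For the genotype difference they ran from 4 (without KO_1d_MWCNT 2) to 204 (without WT_1d_MWCNT 2) and from 0 to 2 (without KO_28d_MWCNT 2), for controls from 5 (without KO_1d_control 1 or 4) to 10 and from 5 to 6, and for the time difference from 1036 to 1779 and 161 (without KO_1d_MWCNT 3) to 296. WT day 28 also fell to 397, 440 and 455 without WT_28d_control 2, WT_28d_control 4 and WT_28d_MWCNT 4, and KO day 28 to 477 without KO_28d_control 2. The day 1 genotype difference left 1.5 times its count without 17 of the 19 arrays.

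Of 31 lists, the estimated correlation called 7, 3, 6 and 5 in the exposures (WT and KO day 1, WT and KO day 28; 19, 13, 13 and 12 with fry), and 1 and 1 for the time difference in WT and KO (11 and 4 with fry). Median centring called 12, 3, 7 and 4 in the exposures, and 3 and 0 for the time difference. The preset correlation called 7 and 10 for the genotype difference at day 1 and 28 (3 and 0 with fry), 3 and 3 for the controls (1 and 0 with fry), and 18 and 13 for the time difference. Without the high-score arrays 1 was called for the day 1 genotype difference, 0 for day 1 controls and 7 for the time difference in WT, and with the liver covariate 0 for day 1 controls. The liver marker list in WT day 1, up in the fit to all 38 arrays, was down without the high-score arrays (adjusted p = 0.946, as a family of 1 list), as their removal would give. Signal over background limits dim genes: 29954 to 44279 of 55681 probes were well above background per array.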

Other observations

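The comparisons below were chosen after the data were seen.

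In all 4 exposures 91 genes were called in the same direction. Those with the largest day 28 change in WT included Gpnmb (1.15 and 1.13 at day 1 in WT and KO, 3.84 and 4.05 at day 28), Slc26a4 (2.59, 2.23, 3.56 and 3.19), Wfdc17 (1.58, 1.23, 3.07 and 2.82), the neutrophil chemokine receptor Cxcr1 (1.57, 1.53, 2.75 and 2.32) and Ccl9 (1.14, 1.03, 2.70 and 2.56). The stress cytokine Gdf15 (1.54, 1.33, 1.85 and 1.70), the cholesterol hydroxylase Ch25h (3.02, 2.53, 1.83 and 1.59), the alarmin Il33 (1.67, 1.76, 1.72 and 1.87) and the matrix protease Mmp19 (1.28, 1.38, 2.07 and 1.81) were among them, as were the falls of Colq (-1.57, -1.33, -1.01 and -1.04) and Scube2 (-1.23, -1.01, -0.70 and -0.56). Cxcr1, Gdf15, Ch25h, Mmp19 and Scube2 were named after their values were seen. Of 257 genes called at both days in WT 235 kept their sign, 6 went from up to down and 16 from down to up; in KO these counts were 180, 4 and 2 of 186.

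Npy, a neuropeptide of nerves and some phagocytes, stood at 0.03 ± 0.18 in WT and 0.06 ± 0.19 in KO at day 1, and rose by 2.91 ± 0.19 and 3.13 ± 0.18 at day 28. It was near background in controls and at day 1, so the size of these rises is uncertain. The antibody joining chain gene Jchain (1.53 ± 0.38) and the plasma cell gene Derl3 (1.18 ± 0.28) rose in WT at day 28, and in KO they stood at 1.16 ± 0.35 and 0.90 ± 0.26 (adjusted p = 0.0754 and 0.0582). The B and plasma cell list was not called at day 28.

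The reference channel holds the same RNA pool on every array. Tested alone it gave 24 called genes of 28173 for WT day 1, 6 for KO day 1, 6 and 12 for WT and KO day 28 and 1 for the time difference in WT. In the other 5 comparisons limma called 0, with 751, 463, 716, 464 and 758 genes at an unadjusted p under 0.05. Among called genes with several probes the probes differed in sign for 241 of 1208 genes in WT day 1, 72 of 420 in KO day 1, 11 of 165 in WT day 28 and 12 of 203 in KO day 28. The closest 2 arrays, KO_1d_control 2 and 3, correlated across probes at r = 0.997, and 1.33% of their values were identical.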
